A study of Sus scrofa with 29 samples.

How the data were processed

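The data are single-colour oligonucleotide array values from luminal scrapes of the brachial and internal mammary arteries of exercise-trained and sedentary pigs. Per the labels, full training load was reached at week 10 and a bout lasted 85 min (5 min of warm-up, a sprint of 15 min, 60 min of endurance running and 5 min of cool-down). Arteries were scraped into a lysis reagent, and the labelled RNA was primed from the poly(A) tail. The deposited values are log2 probe set intensities that the authors computed; affy is named in their processing notes without a version. Their summary method, background correction and normalization are not stated. The arrays had close medians, but those of brachial arrays were lower in 14 of 14 pigs (brachial minus internal mammary -0.0516). Whether both arteries were normalized together is therefore unknown. No gene centring is visible. Values ranged from 2.0 to 14.8, and correlations between arrays ran from 0.965 to 0.995. No scanner files were at hand, so signal over background could not be measured per probe.

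Of the 24123 probe sets, 124 control probe sets were left out of the tests and used for quality checks, leaving 23999. By the deposited platform annotation 10069 of these had 1 gene symbol, 198 had several and 13732 had none. Probe sets with no symbol or several were tested and counted but not named. The symbols made up 6765 genes, and the Entrez identifiers of 9961 probe sets were found in the reference gene table, which was used for names alone. Groups came from the titles and treatment tags. The source field of the 8 exercised internal mammary samples reads sedentary, against their titles, tags and the same pigs' brachial samples, and the titles were followed. All 29 arrays were kept.

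The arteries were paired by pig as the labels state. As a check, each pig's brachial profile was compared with every internal mammary profile after removing group means. The own pair had the highest correlation in 7 of 14 pigs, with a median of 0.190 against -0.0230 between different pigs.

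Each probe set was fitted in limma 3.58.1 (R 4.3.3) with 4 group means and pig as a random block (consensus correlation 0.255), with moderated tests and Benjamini-Hochberg adjustment, at a threshold of 0.05. Contrasts were exercised minus sedentary in each artery, their average, their difference (the interaction) and brachial minus internal mammary. Tables were read with the packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

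Gene lists, 33 in number (10 of cell type markers and 23 of pathways or gene families), were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. A list needed 3 measured members, and each gene was represented by the probe set with the highest mean. Each pig entered a list test once: the arrays of 1 artery, the mean of both arteries, or their difference within the pig. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it.

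Named genes were chosen by rule: the 12 largest rises and falls among genes passing in a comparison, or where fewer than 10 passed, all of these and the 5 rises and falls with the smallest p. To these came up to 4 members of each list described, by smallest p, and 14 genes of vascular function fixed for the exercise comparisons. LAPTM5 and the members printed by name in counts were added after their values were seen. The rule, the lists, the tests and most alternatives were fixed before the data were examined. The alternatives on collection period (also with each pig of a period left out), the macrophage covariate (also in each artery) and the actin covariate were chosen after seeing the data.

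The mean of each marker list was compared between groups by two-sided exact permutation tests (30 tests), with sign flips within pigs between arteries. Control probe sets and label values were compared in the same way (27 tests), each family adjusted by Benjamini-Hochberg. The correlation of the exercise changes between arteries was set against relabelled pigs, as was the number of probe sets shared by the arteries, which was added after seeing the data and took as many probe sets with the smallest p in each direction as had passed. Correlations between pigs used 1e+05 resamples, and random gene sets numbered 1000. Each count was also compared with other divisions of the pigs into groups of the same sizes, or with the arteries exchanged within pigs, 100 in all with the real one.

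Alternatives were no pig block, pig as a fixed block, leaving out the dimmest 33.3% of probe sets, centring or quantile-normalizing the arrays again, a trended robust prior, array weights, and covariates for the 28S/18S ratio, days of collection and smooth muscle markers. The fixed block fitted each artery alone, or the means or within-pig differences of both arteries. Each pig was left out in turn. Collection period was defined from the data, by the step of the 28S probe of the internal mammary arrays in order of collection (11.0 ± 0.736 in 8 early and 13.8 ± 0.298 in 7 late pigs).

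The fit was tested on simulated data with 23999 probe sets, of which 100 changed by each of 2 sizes. A log2 change of 1 was recovered in 95% and a change of 0.5 in 70% of them for the brachial artery, in 94% and 75% for the internal mammary artery and in 96% and 86% for the average, with 8, 12 and 11 false calls. With no interaction simulated, 0 were called. Errors were drawn independently between probe sets, and both arteries got the same change. The false calls therefore do not measure error where probe sets vary together, as on real arrays. Among 33 simulated lists of 20 independent genes, camera called the 1 shifted list and 1 other.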

Results

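RNA was measured in the inner lining scraped from 2 arteries of exercise-trained and sedentary healthy pigs. The scrapes, taken from the brachial artery of the foreleg and from the internal mammary artery of the chest wall, were enriched in endothelial cells. The trained pigs ran on a treadmill 5 days a week for 16 to 20 weeks and were sampled 24 h after the last bout. Single-colour porcine oligonucleotide arrays gave 7 sedentary and 8 exercised internal mammary samples, and 7 sedentary and 7 exercised brachial samples. The 29 arrays came from 15 pigs, of which 14 gave both arteries, and 1 exercised pig gave the internal mammary artery alone. The 8 pigs collected first are called early and the 7 collected last late, parted where the 28S rRNA probe of the internal mammary arrays stepped up. Each array held 23999 probe sets other than controls, with array medians of 7.1 to 7.3 on the log2 scale. Arrays carry no read depth, and their number limits the precision. A value after ± is the SE for a log2 change and the SD for a group mean. Changes and adjusted p-values come from limma across all probe sets, which weighs both arteries of a pig, so a change need not equal the plain difference of group means. A gene is said to have risen or fallen where its adjusted p was under 0.05.

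The first comparison asked which transcripts differed with training in the brachial artery (7 exercised and 7 sedentary pigs). MSMB, a secreted protein best known from the prostate, rose 9.35-fold (log2 change 3.23 ± 0.49, adjusted p = 0.00179). Its mean went from 9.89 ± 1.43 to 13.06 ± 0.65. SERPINE2, an inhibitor of thrombin and plasminogen activators, rose 4.03-fold (2.01 ± 0.26, adjusted p = 0.000188), and the granin SCG2 rose 3.99-fold (2.00 ± 0.36, adjusted p = 0.00665). The IgG Fc receptors FCGR2B and FCGR3A fell, FCGR2B by 2.88-fold (log2 change -1.52 ± 0.20, adjusted p = 0.000316) and FCGR3A by 2.21-fold (-1.14 ± 0.22, adjusted p = 0.00886). DBP, a transcription factor driven by the circadian clock, rose 2.09-fold (1.06 ± 0.19, adjusted p = 0.00665). With the macrophage marker mean as a covariate DBP gave 0.64 ± 0.20 and did not pass (adjusted p = 0.242).

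Other large brachial rises were those of SERPINB7 (2.74-fold), the deubiquitinase USP2 (2.69-fold), the cysteine-degrading enzyme CDO1 (2.45-fold), TMEM25 (2.10-fold) and CAPSL (2.04-fold). CDA, TUSC3 and SERINC2 rose by log2 changes of 0.92 ± 0.17, 0.91 ± 0.22 and 0.89 ± 0.17. The largest fall was that of VNN2, a pantetheinase of the vanin family (log2 change -1.78 ± 0.28, 3.44-fold, adjusted p = 0.00367), followed by the ubiquitin ligase MARCH3 (-1.73 ± 0.40, 3.31-fold, adjusted p = 0.025). Next among the 12 largest falls were CD53, a leukocyte tetraspanin (-1.05 ± 0.22), PLEK, a protein kinase C substrate of platelets and leukocytes (-0.97 ± 0.22), BLNK, an adaptor of the B cell receptor (-0.96 ± 0.19), and FCER1G, the signalling chain shared by Fc receptors (-0.88 ± 0.21). EPB41L3 (-0.97 ± 0.19), the importin KPNA2 (-0.93 ± 0.22), the growth arrest gene GADD45A (-0.92 ± 0.21) and FGD4 (-0.89 ± 0.22) completed them. Each of these 24 genes, which were picked for passing on these same arrays, lay beyond the sedentary mean in 7 of 7 exercised pigs.

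Macrophage markers were the list with the smallest p in the brachial artery. Of its 9 measured members, 0 rose, 3 fell and 6 did not pass, and 5 fell when adjusted over the list alone. The complement gene C1QC fell (-0.81 ± 0.18, adjusted p = 0.0228), as did FCER1G and its partner adaptor TYROBP (-0.66 ± 0.16, adjusted p = 0.0259), while AIF1 gave -0.57 ± 0.19 (adjusted p = 0.12). LAPTM5, the member with the highest array value, gave -0.15 ± 0.15 (adjusted p = 0.704). The list's median was -0.57, with a camera adjusted p = 8.08e-06 and an adjusted p = 0.753 with an estimated correlation. The macrophage marker mean was -0.427 ± 0.208 in exercised and 0.116 ± 0.361 in sedentary brachial scrapes, a difference of -0.543 with 7 of 7 exercised pigs below the sedentary mean (two-sided exact permutation p = 0.00408, adjusted p = 0.0612 over 30 marker tests). By period of collection the difference was -0.368 in the early pigs (exact permutation p = 0.286) and -0.689 in the late pigs (exact permutation p = 0.0286, the smallest possible). Without sedentary pig 12_3, whose marker mean was 0.804, the early difference was -0.130 (exact permutation p = 0.5, where 0.1 is the smallest possible).

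Genes of cholesterol synthesis and uptake lay higher in exercised brachial scrapes, with 2 of 9 members risen, 0 fallen and 7 not passing, and 6 risen when adjusted over the list alone. The sterol demethylase CYP51 rose (0.65 ± 0.12, adjusted p = 0.0082), as did squalene synthase FDFT1 (0.56 ± 0.14, adjusted p = 0.0289). The list's median was 0.56 (camera adjusted p = 0.000304, and adjusted p = 0.753 with an estimated correlation). Of 23 heat shock and unfolded protein genes, 0 rose, 1 fell and 22 did not pass, with 7 fallen when adjusted over the list alone. The chaperone HSPA8 fell (-0.51 ± 0.10, adjusted p = 0.00854), and its cochaperone DNAJA1 gave -0.57 ± 0.15 (adjusted p = 0.0513). That list's median was -0.11 (camera adjusted p = 0.000138, and adjusted p = 0.753 with an estimated correlation), and its mean of -0.171 became -0.0557 with the macrophage covariate (camera adjusted p = 0.327). Of 24 interferon response genes, 0 passed, 4 rose when adjusted over the list alone, and 22 had positive changes, such as IFI44L (0.46 ± 0.13, adjusted p = 0.0595) and IFIT3 (0.65 ± 0.19, adjusted p = 0.0734). Their median was 0.36 (camera adjusted p = 0.000806, and adjusted p = 0.753 with an estimated correlation), and their mean of 0.281 became 0.208 in the early pigs alone (camera adjusted p = 0.0789). Chance was not excluded for the number of lists passing: 4 did so here, and another division of the same pigs gave 11.

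Of 15 measured genes of nitric oxide and prostacyclin vasodilation, 0 rose or fell in the brachial artery, and 1 fell when adjusted over the list alone (HSP90AA1, -0.26 ± 0.07). Their mean change was 0.02, but their median of -0.05 and camera had the opposite sign (adjusted p = 0.764, and adjusted p = 0.926 with an estimated correlation). The endothelial nitric oxide synthase NOS3 gave -0.10 ± 0.11 in the brachial and 0.08 ± 0.11 in the internal mammary artery. Among other genes fixed for the exercise comparisons, endothelin EDN1 gave -0.43 ± 0.28 and -0.14 ± 0.27, and the shear-responsive factor KLF2 gave 0.37 ± 0.16 and -0.00 ± 0.15 in the same order. The dismutases SOD1, SOD2 and SOD3 gave 0.04, -0.39 and 0.17 in the brachial and 0.07, -0.57 and 0.01 in the internal mammary artery. Catalase (CAT) gave 0.25 and 0.22, HMOX1 gave -0.25 and -0.05, and the NADPH oxidase subunit GP91-PHOX gave -0.57 and -0.08. The adhesion molecules VCAM1, ICAM1 and SELE gave 0.10, -0.24 and -0.49 in the brachial and 0.02, -0.02 and -0.71 in the internal mammary artery. The chemokine CCL2 gave -1.23 ± 0.50 (adjusted p = 0.217) and -1.24 ± 0.49 (adjusted p = 0.258). None of these fixed genes passed in either artery or in their average, and NOX4 had no probe set by symbol.

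In all, 392 probe sets passed in the brachial artery, 245 higher and 147 lower in exercised pigs, with a median size of 0.472 on the log2 scale. They held 179 genes by symbol, 119 higher and 60 lower. With the macrophage marker mean as a covariate 7 passed, with the brachial arrays fitted alone in place of the replicate block 122 passed, and with the smooth muscle marker mean as a covariate 753 passed. The difference of the 3' and 5' actin probe sets as a covariate gave 591. The 8 early pigs alone gave 11, and the 7 late pigs alone gave 0 by limma, with 2355 at an unadjusted p under 0.05. Without pig 12_5 the count was 149, without 10_5 it was 154, without 17_1 it was 226, without 15_2 it was 227, and without 15_4 it was 589.

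**Figure D1:**
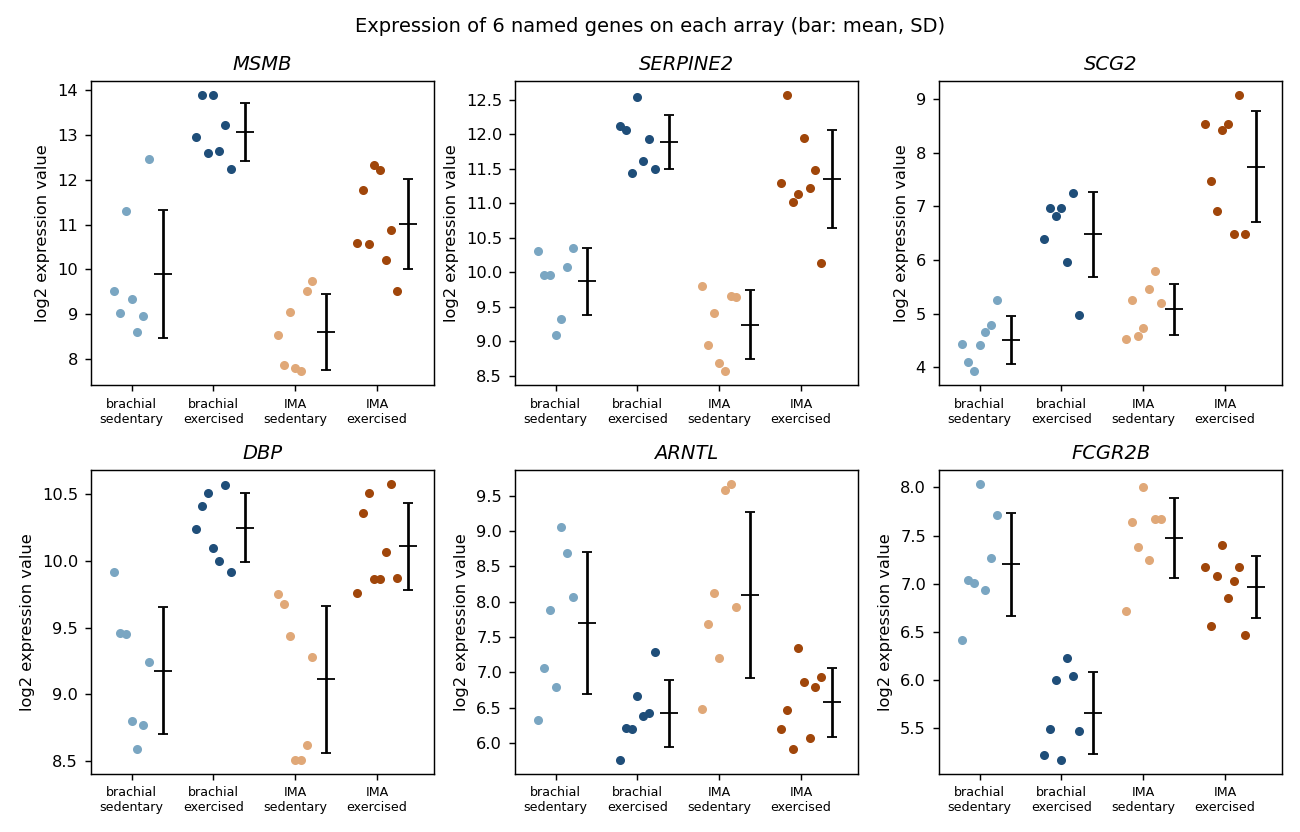
Log2 value of MSMB, SERPINE2, SCG2, DBP, ARNTL and FCGR2B on each array (1 point per array) in the 4 groups of artery and training, with bars at the group mean ± SD. In brachial scrapes FCGR2B averaged 7.20 ± 0.54 in sedentary and 5.66 ± 0.43 in exercised pigs, and SERPINE2 averaged 9.87 ± 0.48 and 11.88 ± 0.39.

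**Figure D2:**
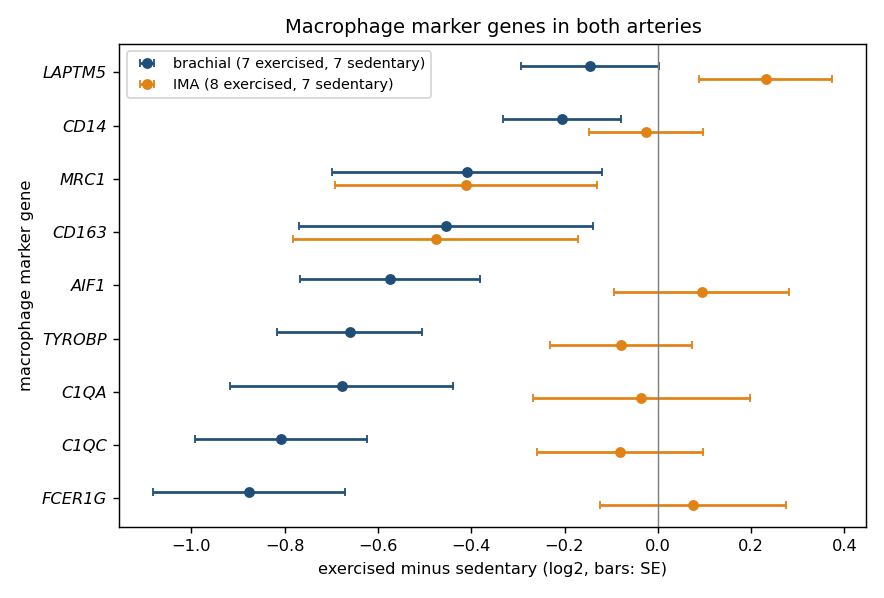
Log2 change (exercised minus sedentary, ± SE from limma) of the 9 measured macrophage markers in the brachial and the internal mammary artery. In the brachial artery 9 of 9 lay below 0, from -0.15 for LAPTM5 to -0.88 for FCER1G.

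The second comparison asked the same of the internal mammary artery (8 exercised and 7 sedentary pigs). SCG2 rose 6.32-fold (log2 change 2.66 ± 0.34, adjusted p = 0.00024), from 5.08 ± 0.48 to 7.74 ± 1.03. MSMB rose 5.31-fold (2.41 ± 0.47, adjusted p = 0.0159) and SERPINE2 rose 4.31-fold (2.11 ± 0.25, adjusted p = 8.13e-05). CD79B, a chain of the B cell receptor, rose 2.76-fold (1.46 ± 0.31, adjusted p = 0.0244), and DBP rose 1.99-fold (1.00 ± 0.19, adjusted p = 0.0128). Follistatin (FST), which binds activins, fell 2.35-fold (-1.23 ± 0.29, adjusted p = 0.043), and the nuclear receptor NR2F1 fell 2.11-fold (-1.08 ± 0.22, adjusted p = 0.0219).

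CAPSL (2.42-fold), CDO1 (2.36-fold) and FAM13A (2.32-fold) rose in the internal mammary artery, as did the G protein subunit GNG2 (0.89 ± 0.20), the erythropoietin receptor EPOR (0.87 ± 0.21), galectin-3 (LGALS3, 0.85 ± 0.17) and SMTNL2 (0.82 ± 0.19). The other 8 falls were smaller: MTFR1 (-0.53 ± 0.12), the ATP synthase subunit ATP5J (-0.52 ± 0.12), the chaperonin subunit CCT6A (-0.50 ± 0.11), HSPA8 (-0.47 ± 0.09), the helicase DDX39A (-0.40 ± 0.09), GNAZ (-0.39 ± 0.09), ROGDI (-0.26 ± 0.06) and the splicing factor RBM17 (-0.25 ± 0.05). ATP5J and ROGDI had further probe sets of the opposite sign. The named risers and fallers, also picked for passing on these arrays, lay beyond the sedentary mean in 8 of 8 exercised pigs, except CDO1 with 7 of 8. The 28S/18S ratio in the labels, a measure of RNA integrity, was higher in these exercised samples as well, at 1.33 ± 0.0841 against 1.19 ± 0.0763. The difference was 0.144, with 8 of 8 exercised pigs above the sedentary mean (two-sided exact permutation p = 0.00544, adjusted p = 0.0184 over 27 tests). It was 0.185 in the early pigs (exact permutation p = 0.0286, the smallest possible) and 0.0967 in the late pigs (exact permutation p = 0.4). The 3' minus 5' difference of the actin probe sets was smaller in these exercised samples, at 1.26 ± 0.111 against 1.43 ± 0.292, with 8 of 8 pigs below the sedentary mean (-0.162, exact permutation p = 0.164, adjusted p = 0.403). It was -0.0538 in the early pigs (exact permutation p = 0.743) and -0.322 in the late pigs (exact permutation p = 0.0286, the smallest possible). The same differences for GAPDH (-0.131, exact permutation p = 0.137, adjusted p = 0.37) and elongation factor EF1a (-0.0660, exact permutation p = 0.213, adjusted p = 0.479) lay below the sedentary mean in 7 of 8 pigs each.

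Cell cycle genes had the smallest list p in the internal mammary artery: 18 of 19 members had positive changes and 0 passed, while 10 rose when adjusted over the list alone. The replication helicase subunit MCM2 gave 0.52 ± 0.13 (adjusted p = 0.0507) and topoisomerase TOP2A gave 1.07 ± 0.27 (adjusted p = 0.0615). The list's median was 0.30 (camera adjusted p = 4.21e-06, and adjusted p = 0.932 with an estimated correlation). Of 24 interferon response genes, 1 rose, 0 fell and 23 did not pass, with 9 risen when adjusted over the list alone. IFI44L rose (0.55 ± 0.12, adjusted p = 0.0318) and MX1 gave 0.57 ± 0.14 (adjusted p = 0.0607). Their median was 0.34 (camera adjusted p = 0.000135, and adjusted p = 0.932 with an estimated correlation). With the 28S/18S ratio as a covariate their mean of 0.342 became 0.0860 (camera adjusted p = 0.465). Of 16 genes of swine leukocyte antigens and antigen presentation, 0 passed, 7 rose when adjusted over the list alone, and SLA-DMB gave 0.48 ± 0.12 (adjusted p = 0.063). Their median was 0.22 (camera adjusted p = 0.000317, and adjusted p = 0.932 with an estimated correlation).

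The other 4 lists that passed in the internal mammary artery were lower in exercised pigs. Of 39 oxidative phosphorylation genes, 0 rose, 1 fell (ATP5J) and 38 did not pass, and the same 1 fell when adjusted over the list alone (median -0.06, camera adjusted p = 0.00033, and adjusted p = 0.932 with an estimated correlation). Of 58 ribosomal protein genes, 0 passed, also when adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.00316, and adjusted p = 0.932 with an estimated correlation). Their mean went from -0.0362 to -0.0214 without pig 11_1 (camera adjusted p = 0.174) and to -0.0216 with the 28S/18S covariate (camera adjusted p = 0.276). Of 23 heat shock and unfolded protein genes, 1 fell (HSPA8), 0 rose and 22 did not pass, and 5 fell and 1 rose when adjusted over the list alone. HSPH1 gave -0.62 ± 0.16 (adjusted p = 0.067), and that list's median was -0.09 (camera adjusted p = 0.0103, and adjusted p = 0.932 with an estimated correlation). Without pig 12_3 its mean went from -0.140 to -0.0658 (camera adjusted p = 0.0755). Of 15 smooth muscle markers, 15 had negative changes and 0 passed, also when adjusted over the list alone, with TPM2 at -0.52 ± 0.36. Their median was -0.31 (camera adjusted p = 0.049, and adjusted p = 0.932 with an estimated correlation), and in the late pigs alone the list's mean was 0.0400. Their mean of -0.290 (exact permutation p = 0.36, adjusted p = 0.788 for the marker mean) became -0.121 without sedentary pig 11_1 (camera adjusted p = 0.71), which had the highest marker mean (1.08), and -0.443 without exercised pig 14_3. With the 28S/18S covariate it was -0.171 (camera adjusted p = 0.465). The camera call ended without 9 of 15 pigs: 10_1, 10_5, 11_1, 11_3, 12_2, 12_5, 15_1, 15_4 or 17_1. Of 9 macrophage markers 0 passed, with a median of -0.04 (camera adjusted p = 0.849, and adjusted p = 0.932 with an estimated correlation). Of the 7 lists that passed, 4 passed again with the same sign with the 28S/18S covariate and 1, the heat shock list, in the late pigs alone. Chance was not excluded for their number, since another division of the pigs gave 14.

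In the internal mammary artery 143 probe sets passed, 110 higher and 33 lower in exercised pigs, with a median size of 0.572 on the log2 scale. They held 53 genes by symbol, 43 higher and 10 lower. The internal mammary arrays fitted alone in place of the replicate block gave 13 probe sets. Array weights gave 337, the 28S/18S ratio as a covariate gave 273, the actin covariate 254, the smooth muscle covariate 253 and a factor for early or late collection 227. The early pigs alone gave 5, and the late pigs alone gave 0 by limma, with 1662 at an unadjusted p under 0.05. Without pig 10_5 the count was 35, without 11_3 it was 47, without 13_2 it was 59, without 12_3 it was 60, and without 15_2 it was 64. Without pig 11_1 it was 72, without 15_1 79, without 10_1 86, without 12_5 91, without 14_3 239 and without 10_2 291.

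Averaged over both arteries, MSMB rose 7.05-fold (log2 change 2.82 ± 0.38, adjusted p = 0.000178), SCG2 5.02-fold (2.33 ± 0.28, adjusted p = 2.82e-05) and SERPINE2 4.17-fold (2.06 ± 0.20, adjusted p = 1.16e-06). CHI3L1, a secreted chitinase-like glycoprotein, rose 5.05-fold (2.34 ± 0.48, adjusted p = 0.00488). Clock genes moved in both directions. DBP rose 2.04-fold (1.03 ± 0.15, adjusted p = 0.000339), while the core clock activator ARNTL fell 2.61-fold (-1.39 ± 0.30, adjusted p = 0.00719). ARNTL gave -1.25 ± 0.38 in the brachial (adjusted p = 0.0851) and -1.52 ± 0.37 in the internal mammary artery (adjusted p = 0.0507). With the macrophage marker mean as a covariate, ARNTL gave -1.21 ± 0.34 (adjusted p = 0.0658) in the average.

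Of 7 clock genes, 1 rose, 1 fell and 5 did not pass, and 2 rose and 1 fell when adjusted over the list alone. CRY2 gave 0.42 ± 0.15 (adjusted p = 0.0964). The list's mean was 0.00 and its median 0.16 (camera adjusted p = 0.808, and adjusted p = 0.981 with an estimated correlation). USP2 (2.41-fold), CDO1 (1.27 ± 0.21), the matrix protein CILP (2.24-fold), CAPSL (1.15 ± 0.21), interleukin 6 (IL6, 2.16-fold, adjusted p = 0.0479), CD79B (1.06 ± 0.24) and FAM13A (1.01 ± 0.18) rose as well. Beside ARNTL, the averaged falls were MARCH3 (2.96-fold), VNN2 (2.46-fold), FCGR2B (2.02-fold), the cofilin phosphatase SSH1 (-0.96 ± 0.24), FST (-0.95 ± 0.23) and the vasodilator peptide adrenomedullin (ADM, 1.92-fold). KPNA2, PITPNC1, NR2F1, GADD45A and EPB41L3 fell by 0.75, 0.71, 0.69, 0.68 and 0.67 on the log2 scale. Exercised pigs lay beyond the sedentary mean in 7 of 7 brachial scrapes for each named riser and faller (6 of 7 for NR2F1) and in at least 7 of 8 internal mammary scrapes. These genes were picked for passing on the same arrays.

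Interferon response genes lay higher in exercised pigs over both arteries, with 6 of 24 risen, 0 fallen and 18 not passing, and 12 risen when adjusted over the list alone. IFI44L (0.50 ± 0.10, adjusted p = 0.00357), MX1 (0.53 ± 0.12, adjusted p = 0.0078), IFIT3 (0.62 ± 0.15) and IRF9 (0.41 ± 0.10) rose. The list's median was 0.37 (camera adjusted p = 0.00161, and adjusted p = 0.962 with an estimated correlation). Of 16 antigen presentation genes 3 rose (SLA-DMA, SLA-DMB and SLA-DOA), 0 fell and 13 did not pass, with 4 risen when adjusted over the list alone (median 0.16, camera adjusted p = 0.00581, and adjusted p = 0.981 with an estimated correlation). Of 9 cholesterol genes 2 rose (CYP51 and FDFT1), 0 fell and 7 did not pass, with 3 risen when adjusted over the list alone (median 0.34, camera adjusted p = 0.00359, and adjusted p = 0.962 with an estimated correlation). Of 19 cell cycle genes 2 rose (MCM2 and MCM5), 0 fell and 17 did not pass, with the same number when adjusted over the list alone (median 0.25, camera adjusted p = 0.0201, and adjusted p = 0.981 with an estimated correlation). The cell cycle mean of 0.205 became 0.107 without pig 10_1 (camera adjusted p = 0.168), and the call also ended without 11_1 or 11_4.

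Heat shock genes lay lower over both arteries, with 0 of 23 risen, 6 fallen and 17 not passing, and 8 fallen and 1 risen when adjusted over the list alone. HSPA8 (-0.49 ± 0.08, adjusted p = 0.000504), HSPH1 (-0.59 ± 0.13), HSP70.2 (-0.49 ± 0.11) and DNAJA1 (-0.53 ± 0.12) fell. The list's median was -0.11 (camera adjusted p = 0.00161, and adjusted p = 0.962 with an estimated correlation), and its mean of -0.163 became -0.105 without pig 12_3 and -0.0590 with the macrophage covariate (camera adjusted p = 0.272). Of 9 macrophage markers 0 passed, with 2 fallen when adjusted over the list alone (median -0.37, camera adjusted p = 0.00452, and adjusted p = 0.962 with an estimated correlation). Of 15 smooth muscle markers 0 passed, also when adjusted over the list alone (median -0.28, camera adjusted p = 0.0044, and adjusted p = 0.981 with an estimated correlation). Of 39 oxidative phosphorylation genes 1 fell (ATP5J), 0 rose and 38 did not pass, with the same 1 when adjusted over the list alone (median -0.05, camera adjusted p = 0.0334, and adjusted p = 0.981 with an estimated correlation). That call ended without 8 of 15 pigs (10_1, 10_2, 11_1, 11_4, 14_3, 15_2, 15_4 or 17_1). Of the 8 lists that passed, 4 passed again with the same sign with the smooth muscle covariate and 3 in the late pigs alone. Chance was not excluded for their number, since another division of the pigs gave 11.

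In the average over both arteries 1123 probe sets passed, 690 higher and 433 lower, which held 511 genes by symbol, 316 higher and 195 lower. With pig ignored, 1996 passed, and with pig means in place of the replicate block 364. The macrophage covariate gave 336, the early pigs alone 252 and the late pigs alone 28. Without pig 10_5 the count was 705, and without pig 11_3 it was 724.

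More of the changes were shared by the arteries than in relabelled pigs. Of the 245 probe sets higher with training in the brachial and the 110 in the internal mammary artery, 47 were shared, and of the 147 and 33 lower ones 21 were shared. Independent sets would share 1.12 and 0.202, but both arteries came from the same pigs, so relabelled pigs set the baseline. Among the same numbers of probe sets with the smallest p, relabelled pigs shared a median of 13 and at most 34 higher ones, and a median of 5 and at most 17 lower ones. Of the 467 probe sets passing in either artery, which were picked for passing, 96.1% had the same sign in both. Of all probe sets 70.8% did, against a median of 59.8% with relabelled pigs. By symbol 27 genes passed in both arteries, 22 higher, among them MSMB, SERPINE2, SCG2, CDO1, DBP, the collagen COL8A1, the basement membrane protein NID2, galectin-3 (LGALS3) and the mitochondrial deacetylase SIRT3, and 5 lower, namely RBM17, DDX39A, CCT6A, HSPA8 and ATP5J. Across all probe sets, which are not independent replicates, the changes correlated with a Pearson r of 0.637 and a Spearman rho of 0.600. With relabelled pigs the median r was 0.339 and the highest 0.613. The covariance of the changes was 0.0250, against a mean of 0.00546 and a highest value of 0.0166 with relabelled pigs. Within the early pigs r was 0.519 and within the late pigs 0.433, where relabelled pigs reached 0.597 and 0.541.

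**Figure D3:**
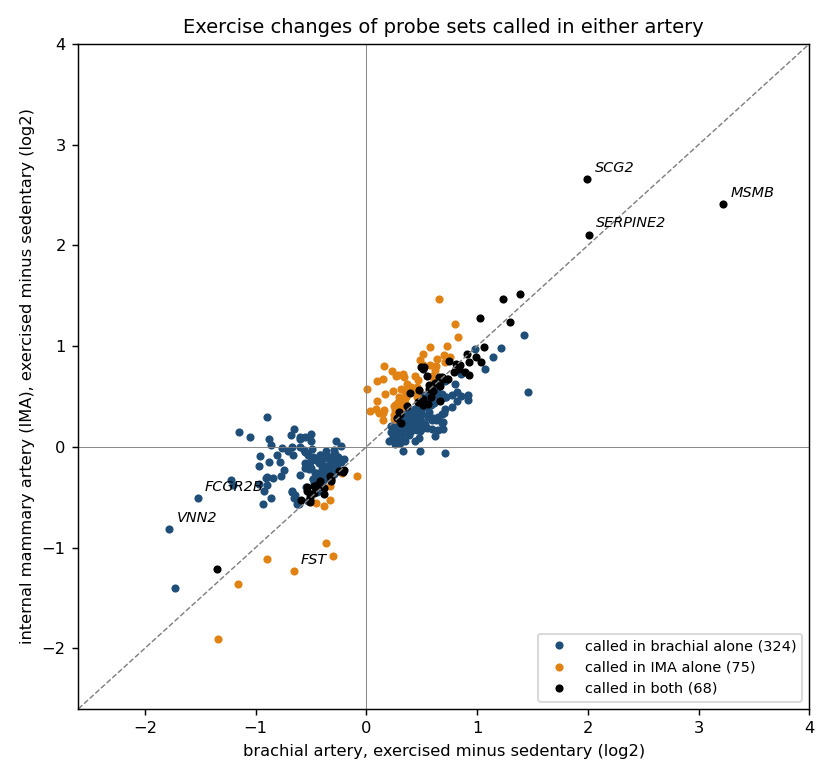
Log2 change with training in the brachial artery (x axis) against that in the internal mammary artery (y axis) for the 467 probe sets passing in either; colours mark those passing in the brachial artery alone (324), in the internal mammary artery alone (75) or in both (68). MSMB, SERPINE2 and SCG2 lie at the upper right, above 2-fold in both arteries.

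The test of whether training acted differently in the arteries found no gene that passed. For the exercise by artery interaction limma called 0 probe sets (smallest adjusted p = 0.227), with 1035 at an unadjusted p under 0.05. The count was also 0 with pig ignored and with pig as a fixed replicate block, 4 with the smooth muscle covariate and 1 without pig 10_1. The negative values with the smallest p were those of FCGR3A (-1.30 ± 0.27, adjusted p = 0.281), CD53 (-1.15 ± 0.27, adjusted p = 0.445), CPM (-0.83 ± 0.18) and the phosphatase PTPN6 (-0.75 ± 0.17, with another probe set of the opposite sign). CACNB4 gave -0.41 ± 0.10. The positive values with the smallest p were those of FLVCR2 (1.21 ± 0.33), UPK3A (0.70 ± 0.19), NNAT (0.37 ± 0.07), PYROXD1 (0.37 ± 0.10) and PPARGC1A (0.33 ± 0.09).

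Among the lists, 9 macrophage markers had a median interaction of -0.58 (0 passing, 4 fallen when adjusted over the list alone, camera adjusted p = 4.4e-08, and adjusted p = 0.0929 with an estimated correlation). Cell cycle genes had a limma mean of -0.27, and -0.253 as the within-pig differences that camera tested (0 passing, 3 fallen when adjusted over the list alone, camera adjusted p = 1.02e-06, and adjusted p = 0.316 with an estimated correlation). Cholesterol genes had a limma mean of 0.34, and 0.312 as within-pig differences (0 passing, camera adjusted p = 3.66e-05, and adjusted p = 0.316 with an estimated correlation). In all 10 lists passed by camera and 0 with an estimated correlation or by fry, and chance was not excluded, since another division of the pigs gave 14 lists.

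The last comparison was between the arteries, brachial against internal mammary, over 14 pigs with both. DPT, a matrix protein of the adventitia, was 4.68-fold higher in brachial scrapes (2.23 ± 0.20, adjusted p = 3.02e-10, higher in 14 of 14 pigs), and the muscle filament desmin (DES) was 4.33-fold higher (2.11 ± 0.36, adjusted p = 1.84e-05, 12 of 14 pigs). The elastic fibre protein MFAP2 (1.61 ± 0.18, 13 of 14 pigs), tenascin TNC (1.56 ± 0.35, 12 of 14) and COMP (1.46 ± 0.29, 12 of 14) were also higher. Fibroblast and adventitia markers averaged 0.477 higher in brachial scrapes (13 of 14 pigs, exact permutation p = 0.000366, adjusted p = 0.011 over 30 marker tests; 0.507 in the early and 0.446 in the late pigs). The immediate early genes BTG2 and FOS were higher in internal mammary scrapes, BTG2 by 5.09-fold (-2.35 ± 0.21, adjusted p = 3.74e-10) and FOS by 4.31-fold (-2.11 ± 0.25, adjusted p = 7.9e-08), each in 14 of 14 pigs. HOXA9, a gene of body axis patterning, was also higher there (-1.70 ± 0.29, adjusted p = 2.05e-05, 13 of 14 pigs).

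EDF1 (1.98 ± 0.06), ATP10A (1.91 ± 0.14), CDO1 (1.66 ± 0.17) and the junction protein JUP (1.45 ± 0.05) were higher in the brachial artery of 14 of 14 pigs, and TPPP3 (1.71 ± 0.21) and MSMB (1.70 ± 0.29) in 13 of 14. LOC100153598 gave 1.59 ± 0.38 (10 of 14 pigs), with another probe set of the opposite sign. Lower in the brachial artery of 14 of 14 pigs were LOC100154873 (-4.01 ± 0.26), ZNF12 (-2.25 ± 0.14), MAN1A1 (-1.87 ± 0.14), RERG (-1.86 ± 0.27), ARHGAP29 (-1.79 ± 0.12) and CPEB2 (-1.68 ± 0.11). The same held for LOX (-1.97 ± 0.13), PDE3A (-1.80 ± 0.11) and ARHGEF12 (-1.66 ± 0.11), each of which had another probe set of the opposite sign.

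Of 16 immediate early genes 12 were lower in the brachial artery, 1 was higher (FOSL1) and 3 did not pass, with the same numbers when adjusted over the list alone. JUN gave -0.99 ± 0.09 and IER2 -0.97 ± 0.12. The list's median was -0.79 (camera adjusted p = 2.37e-05, and adjusted p = 0.994 with an estimated correlation). Of 9 cholesterol genes 7 were higher in the brachial artery, 0 lower and 2 not passing, also when adjusted over the list alone, with SREBF1 at 0.44 ± 0.04 and SQLE at 1.11 ± 0.17 (median 0.34, camera adjusted p = 0.033, and adjusted p = 0.994 with an estimated correlation). Of 58 ribosomal protein genes 5 were higher, 19 lower and 34 not passing, also when adjusted over the list alone, with RPL31 at -0.23 ± 0.03 and RPL30 at 0.46 ± 0.06. That list's median was -0.03 (camera adjusted p = 0.0433, and adjusted p = 0.994 with an estimated correlation), and its mean became 0.0740 when all probe sets of a gene were averaged. That call ended without 7 of 15 pigs (11_1, 12_3, 12_5, 14_3, 15_1, 15_2 or 17_1). Chance was not excluded for the number of lists: 3 passed, and another exchange of the arteries within pigs gave 14.

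Between the arteries 13026 probe sets passed (54.3% of those tested), 7631 higher and 5395 lower in the brachial artery, with a median size of 0.268 on the log2 scale; 388 differed at least 2-fold. The direction of the majority depended on the filter: with the dimmest 33.3% of probe sets left out, 4174 were higher and 4807 lower (46.5% higher, against 58.6%). Control probe sets differed as well. The hybridisation controls, added to every sample at fixed amounts, were 0.626 higher on brachial arrays of 14 of 14 pigs (exact permutation p = 0.000122, the smallest possible, adjusted p = 0.000659; 0.786 in the early and 0.467 in the late pigs). The 3' minus 5' difference of the actin probe sets was 0.906 larger in 14 of 14 pigs, at 2.24 against 1.34. The 28S/18S ratio in the labels was 0.142 higher in brachial samples (11 of 14 pigs, exact permutation p = 0.00635, adjusted p = 0.019). It was 0.257 higher in the early pigs (exact permutation p = 0.0312) and 0.0271 in the late pigs (exact permutation p = 0.312), where it did not pass. The 28S rRNA probe averaged 7.97 on brachial and 12.3 on internal mammary arrays. With the actin difference as a covariate 4850 probe sets passed, and the late pigs alone gave 8596.

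**Figure D4:**
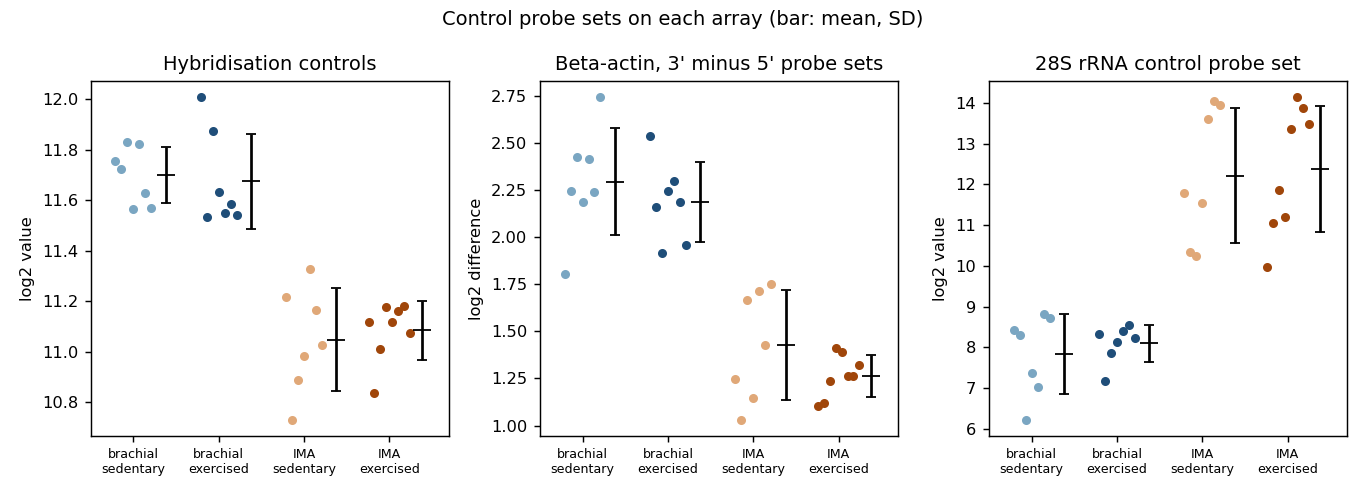
Mean of the hybridisation controls, difference of the 3' and 5' actin probe sets, and 28S rRNA probe on each array (1 point per array, log2 scale), by artery and training. The hybridisation controls of the brachial arrays start at 11.53, above the highest internal mammary array at 11.33.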

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

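The tests of the hybridisation controls, of the actin covariate, of the 28S/18S covariate between arteries and of the macrophage covariate, the values by collection period, the macrophage covariate in each artery and the relabelling counts for the correlation and the overlap between arteries were chosen after the results were seen.

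The clock-linked genes DBP and USP2 were higher and ARNTL was lower in exercised pigs (averaged log2 changes 1.03 ± 0.15, 1.27 ± 0.23 and -1.39 ± 0.30). A difference in RNA quality is argued against as the whole cause of the averaged changes, since with the 28S/18S ratio as a covariate 92.6% of their mean size was left and all of them passed. That ratio differed with training by 0.144 in the internal mammary artery, but by only 0.0386 in the brachial artery. The changes were not weighed within each artery with this covariate, so RNA quality stays open for the internal mammary artery taken alone. A share of macrophages is argued against as the whole cause in the internal mammary artery, where their marker mean differed by -0.0784 (exact permutation p = 0.596) and at least 93.4% of the changes was left with that mean as a covariate, each over 2 SE from 0. It stays open as a part in the brachial artery, where the fits disagreed. With all arrays 79.0% was left (ARNTL -0.95 ± 0.48). With the brachial arrays alone 97.3% was left, a mean in which ARNTL grew, from -1.28 to -1.53 ± 0.54. DBP shrank in both fits, from 1.06 to 0.64 ± 0.20 with all arrays (adjusted p = 0.242) and from 1.07 to 0.78 ± 0.25 alone (adjusted p = 0.453). USP2 kept 1.36 in both but lost its call with all arrays (adjusted p = 0.164). The macrophage share also stays open in the average, where 87.8% was left. There ARNTL went from -1.39 ± 0.30 to -1.21 ± 0.34 and missed the threshold (adjusted p = 0.0658), as its estimate shrank and its error grew. Different hours of collection may also account for it: within groups DBP and ARNTL correlated between 14 pigs (Pearson r -0.597, permutation p = 0.0236, adjusted p = 0.0709 over 3 relations; Spearman rho -0.512, permutation p = 0.0640), though that relation rests on few pigs (r -0.251 without the 2 farthest, -0.135 in early and -0.750 in late pigs), the labels give no hour, and a clock shifted by training cannot be told apart from it.

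For the lower macrophage markers of exercised brachial scrapes, the hypothesis of fewer macrophages predicted that the 9 markers vary together within groups. They did (mean pairwise correlation 0.448, against a 95th percentile of 0.138 for random gene sets), and 0 of the 9 are in another list. Markers of a cell type may also vary together through a change within cells, so this result does not tell these hypotheses apart. The correlation was not computed without sedentary pig 12_3, whose marker mean was 0.804. The members moved unequally: levels from sedentary to exercised went from 10.41 to 9.59 for C1QC, 9.91 to 9.02 for FCER1G and 9.52 to 8.81 for C1QA, but from 11.94 to 11.79 for LAPTM5, a single gene chosen after its value was seen; values of different probe sets do not compare as abundance, and a change within cells stays open and was not tested. RNA quality is argued against, with 99.99% of the list's change left under the 28S/18S covariate, though the ratio differed little there (0.0386, exact permutation p = 0.717) and left little to remove. Collection period stays open: the smaller of the early and late changes was 67.8% of the pooled one (list means -0.368 and -0.689, camera adjusted p = 0.0335 and 1.3e-09), but without sedentary pig 12_3 the early change was -0.130, or 24.0% of the pooled one and 30.5% of that without the pig. The list lost its call with an estimated correlation (adjusted p = 0.753), and the marker mean missed the threshold after adjustment (exact permutation, adjusted p = 0.0612).

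Between the arteries 54.3% of probe sets differed, more than chance gave. RNA integrity as the 28S/18S ratio measures it is argued against as the whole cause, since 10484 of 13026 calls (80.5%) were left with the same sign with that ratio as a covariate; it was 0.142 higher in brachial samples. A larger share of adventitial cells in brachial scrapes stays open, since 7907 calls (60.7%) were left with the same sign with the fibroblast and adventitia marker mean as a covariate, between the bounds set in advance for and against it, and so does a hybridisation batch: the controls were 0.626 higher on brachial arrays, without overlap between arteries, and batch and artery cannot be told apart because no pig had both arteries at like control levels. A bias to the 3' end, from fragments or labelling, stays open as well, since the actin covariate left 3983 of the calls with the same sign (30.6%), between the bounds set for and against it, and the actin and elongation factor probe sets had larger 3' minus 5' differences on brachial arrays (0.906 and 0.300) while that of GAPDH was smaller (-0.257). A biological difference between arteries is also open and untested apart from these.

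Among the data outside the main measurement, 3 signals were taken up. The hybridisation controls differed between arteries by 0.626. The 28S rRNA probe was lower on brachial arrays (-4.41, exact permutation p = 0.000122, the smallest possible). On internal mammary arrays the 28S probe was 2.78 higher in late than in early pigs. The periods were parted at the step of this same probe, so that difference is no test. Free of the cut, the probe correlated with collection date on internal mammary arrays (Pearson r 0.850, permutation p = 0.00024). On brachial arrays r was 0.266 (permutation p = 0.36). Beside these, the 18S rRNA probe was 1.10 higher on brachial arrays, in 13 of 14 pigs (exact permutation, adjusted p = 0.00165). The array median was lower there in 14 of 14 pigs (-0.0516, exact permutation, adjusted p = 0.000659).

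By camera the exercise effect differed between arteries for 10 lists. By limma over all arrays, the brachial minus internal mammary mean log2 was: macrophage -0.456, lymphocyte -0.274, endothelin and angiotensin vasoconstriction -0.197, NADPH oxidase and oxidant sources -0.271, oxidative phosphorylation 0.0506, cholesterol 0.339, immediate early response -0.346, antigen presentation -0.0774, cell cycle -0.270 and ribosomal protein 0.0560. Camera itself tested differences within pigs. Their means were -0.431 for macrophage, -0.245 for lymphocyte, -0.201 for vasoconstriction and -0.267 for NADPH oxidase. They were -0.265 for immediate early response, -0.0732 for antigen presentation and -0.253 for cell cycle. They were 0.0462 for oxidative phosphorylation, 0.312 for cholesterol and 0.0499 for ribosomal protein. With an estimated correlation 0 of them passed. Leaving out 1 of 15 pigs ended the call of antigen presentation for 8 pigs, oxidative phosphorylation for 6, vasoconstriction for 4 and immediate early response for 3. The direction of the immediate early list also turned by camera with the macrophage covariate.

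Other divisions of the pigs set these counts in proportion. For probe sets, no other division drawn called as many in the internal mammary artery (143, 1 of 100, highest other 4) or in the average (1123, 1 of 100, highest other 17). In the brachial artery 392 were called, as many in 2 of 100 divisions. Another division called more there (573), so chance was made unlikely but not excluded. The difference between arteries was also beyond every other exchange drawn (13026, 1 of 100, highest other 7722, where the arteries of 2 of 14 pigs were exchanged). For the interaction 0 were called, so every division had as many by construction (100 of 100, highest other 1005) and the comparison cannot decide. The divisions with 573 and 1005 calls were the same one, with 3 exercised and 2 late pigs among 7. It parted brachial arrays by 1.21 SD in smooth muscle markers, 1.06 SD in the 28S/18S ratio and -0.826 SD in late collection. Whether any of these produced its calls was not tested. The smooth muscle covariate gave 753 brachial calls for the real groups.

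For gene lists chance was not excluded in any comparison: the brachial artery gave 4 (as many in 74 of 100, highest other 11), the internal mammary artery 7 (38 of 100, highest other 14), the average 8 (27 of 100, highest other 11), the interaction 10 (19 of 100, highest other 14) and the arteries 3 (82 of 100, highest other 14). The correlation of the changes between arteries (0.637) was the highest of 100, with 0.613 next (1 of 100). The probe sets shared by the arteries were also more than in every other division drawn, 47 higher (1 of 100, highest other 34) and 21 lower (1 of 100, highest other 17).

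Single samples lay far from the others of their group in 31 of 436 groups tested (76 of measures and marker means, 360 of genes). Chance flags about 1 in 20 groups, or 21.8 here. In the labels, the total RNA amount of exercised pig 15_4 was 340.9 for the internal mammary artery (others 81.2 to 184.8, unit not stated), and the 28S/18S ratio of sedentary pig 10_2 was 1.79 for the brachial artery (others 1.21 to 1.45). Values below are log2, with the range of the others of the group after each.

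In sedentary pig 12_3, SOD2 was 12.44 in the internal mammary (9.83 to 10.54) and 12.69 in the brachial artery (9.67 to 10.35). Its CAT was 11.17 (11.71 to 12.10), CCT6A 11.15 (10.21 to 10.41) and ROGDI 10.42 (10.03 to 10.19) in the internal mammary artery, and SELE was 8.97 (4.38 to 5.88) and KPNA2 10.31 (8.94 to 9.38) in the brachial artery. In exercised pig 10_1, internal mammary IL6 was 10.93 (6.57 to 8.41), GADD45A 11.17 (9.26 to 10.10), SELE 5.74 (4.50 to 5.05) and CILP 7.00 (8.94 to 9.83), and brachial KLF2 was 8.41 (7.07 to 7.62). In exercised pig 14_3, brachial SOD3 was 10.31 (10.60 to 10.78), GP91-PHOX 7.92 (6.84 to 7.29) and SSH1 6.95 (6.05 to 6.43), and internal mammary COMP was 6.83 (5.44 to 5.84) and FOS 11.65 (12.74 to 13.68).

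In exercised pig 15_4, brachial SERINC2 was 7.43 (7.95 to 8.24) and SMTNL2 11.26 (11.94 to 12.33), and internal mammary MARCH3 was 8.34 (5.40 to 6.73). In sedentary pig 15_1, internal mammary SERPINB7 was 7.64 (3.57 to 5.11) and HOXA9 6.94 (9.59 to 11.23), and brachial MAN1A1 was 9.88 (8.31 to 8.94). In sedentary pig 11_1, internal mammary SSH1 was 6.01 (7.73 to 8.92) and COMP 7.55 (5.52 to 5.79). Single values were PPARGC1A at 3.61 in the brachial artery of sedentary pig 11_4 (3.13 to 3.33), PDE3A at 10.78 in the internal mammary artery of exercised pig 15_2 (10.22 to 10.45), ARHGAP29 at 6.91 in the brachial artery of exercised pig 11_3 (7.59 to 8.09) and LOC100154873 at 8.12 in that of exercised pig 12_5 (5.66 to 6.67).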

How the results depend on the processing

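The alternatives on collection period (also with single pigs left out), macrophage markers and actin were chosen after the results were seen. For all that moved, the cause was not tested, except that the period alternatives and those leaving out a pig use fewer samples. The fixed block does so too, since it fitted each artery alone, or the means or within-pig differences of both arteries. Of 126 results for named genes that passed, 0 reversed under any alternative run; 53 lost their call with the fixed block, 45 with the macrophage covariate, 77 in early and 90 in late pigs alone. The filter, both rescalings of the arrays, the trended prior and days of collection left the 5 counts of probe sets within 1.5 times. With arrays centred on their medians 69.4% of probe sets differing between arteries were higher in the brachial artery, against 58.6% as deposited, and with the dimmest 33.3% left out 46.5% were, which turns the majority. Signal over background could not be measured, so what dim probe sets miss is unknown.

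Probe sets passing, in place of 392 (brachial), 143 (internal mammary), 1123 (average), 0 (interaction) and 13026 (arteries): with no replicate block the average gave 1996. With the replicate block as a fixed effect, or its pairing removed by fitting each artery alone, the brachial artery gave 122, the internal mammary artery 13 and the average 364. For the internal mammary artery array weights gave 337, the 28S/18S covariate 273 and the period factor 227. The smooth muscle covariate gave 753 (brachial), 253 (internal mammary) and 4 (interaction). The macrophage covariate gave 7 (brachial) and 336 (average). The actin covariate gave 591 (brachial), 254 (internal mammary) and 4850 (arteries), of which 3983 passed before with the same sign. Early pigs alone gave 11 (brachial), 5 (internal mammary) and 252 (average). Late pigs alone gave 0 by limma in the brachial (2355 at an unadjusted p under 0.05) and 0 in the internal mammary artery (1662), 28 (average) and 8596 (arteries).

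Gene lists passing numbered 4, 7, 8, 10 and 3 in the same order. With an estimated correlation they were 0, 0, 0, 0 and 0, and by fry 0, 0, 1, 0 and 14. Averaging all probe sets of a gene gave 1 and quantile normalization 5 between arteries, the smooth muscle covariate 4 in the average, and late pigs alone 1 (internal mammary), 3 (average) and 5 (interaction). Of the lists passing, those that passed again with the same sign were, with the 28S/18S covariate, 4 (internal mammary; interferon, smooth muscle and ribosomal protein ended), 7 (average; cell cycle ended) and 2 (arteries). With the macrophage covariate they were 2 (brachial; heat shock ended, and macrophage by construction), 6 (average; the same ended) and 6 (interaction). The smooth muscle covariate gave 5 (internal mammary; ribosomal protein ended, and smooth muscle by construction), 4 (average) and 2 (arteries), the period factor 7 (average), 9 (interaction) and 2 (arteries), early pigs 3 (brachial), 6 (internal mammary), 6 (average) and 2 (arteries), and late pigs 1 (internal mammary), 3 (average), 3 (interaction) and 1 (arteries). In 3 lists the direction turned: ribosomal protein between arteries, mean 0.0740 with all probe sets averaged; smooth muscle in the internal mammary artery, 0.0400 in late pigs; and immediate early response in the interaction, camera turning with the macrophage covariate at a mean of -0.0321. The mean of antigen presentation in the interaction, but not camera, also turned in late pigs (0.0245). The correlation between arteries was 0.519 in early and 0.433 in late pigs, against 0.637.

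With all probe sets of a gene averaged, exercised minus sedentary marker means were 0.00120 for endothelium and 0.0197 for Schwann cells in the internal mammary artery, and -0.513 for macrophages in the brachial artery, which then passed (exact permutation, adjusted p = 0.0437).

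Leaving out each pig in turn gave 149 (without 12_5) to 589 (without 15_4) probe sets in the brachial artery, also 154 (10_5), 226 (17_1) and 227 (15_2). In the internal mammary artery it gave 35 (10_5) to 291 (10_2), also 47 (11_3), 59 (13_2), 60 (12_3), 64 (15_2), 72 (11_1), 79 (15_1), 86 (10_1), 91 (12_5) and 239 (14_3). The average ranged from 705 (10_5) to 1223 (15_4), also 724 (11_3), and the interaction from 0 to 1 (10_1). The brachial exercise difference in 28S/18S ran from -0.00905 to 0.108. Marker means ran from -0.0322 to 0.0552 (endothelium, brachial), -0.0197 to 0.0623 (endothelium, between arteries), -0.0291 to 0.0878 (fibroblast, internal mammary), -0.391 (11_1) to -0.0797 (10_2) (smooth muscle, brachial), -0.443 (14_3) to -0.121 (11_1) (smooth muscle, internal mammary), 0.0821 (15_4) to 0.328 (11_1) (smooth muscle, between arteries), -0.614 to -0.428 (macrophage, brachial, passing without 10_1 at -0.594 and without 11_1 at -0.614), -0.136 to 0.00750 (macrophage, internal mammary), -0.330 to -0.250 (macrophage, between arteries, passing without 12_3 at -0.330), -0.208 to 0.114 (erythrocyte, brachial), -0.00101 to 0.644 (erythrocyte, internal mammary), -0.0749 to 0.0531 (platelet, internal mammary) and -0.0707 to 0.0238 (platelet, between arteries).

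Leaving out 1 of 15 pigs ended camera calls for 9 pigs in smooth muscle (internal mammary, means -0.443 to -0.121), 8 in oxidative phosphorylation (average, -0.0751 to -0.0351), 7 in ribosomal protein (between arteries, -0.0310 to -0.0210), 3 in cell cycle (average, 0.107 to 0.243), 1 in ribosomal protein (internal mammary, 11_1, -0.0214) and 1 in heat shock (internal mammary, 12_3, -0.0658). In the interaction, as differences within pigs, it ended those of antigen presentation for 8 pigs (10_1, 10_5, 11_1, 11_3, 12_3, 15_1, 15_4, 17_1; means -0.140 without 10_2 to -0.0176 without 11_1), oxidative phosphorylation for 6 (10_5, 11_1, 11_3, 12_3, 15_1, 15_4; 0.0245 without 11_1 to 0.0749 without 11_4), vasoconstriction for 4 (10_1, 11_1, 11_4, 14_3; -0.257 to -0.156) and immediate early response for 3 (10_1, 10_5, 17_1; -0.325 without 11_3 to -0.166 without 17_1).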

Other observations

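No test in this part was chosen after its result was seen. The shares of all genes passing were set beside the counts afterwards, without a test. The members named are those with the smallest p in lists fixed before.

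Single patterning genes differed between the arteries of the foreleg and the chest wall, where 3488 of 6765 genes of any kind passed. Of 9 measured genes of limb, thorax and heart patterning, 4 were higher in brachial scrapes, 0 lower and 5 not passing, with the same numbers when adjusted over the list alone: the homeobox gene MSX1 (0.59 ± 0.06, adjusted p = 1.66e-09), TBX2 (0.29 ± 0.04), HAND1 (0.27 ± 0.04) and GATA4 (0.28 ± 0.05). Of 6 HOX genes, HOXB7 (-0.58 ± 0.07, adjusted p = 3.24e-08), HOXA9 (-1.70 ± 0.29) and HOXD8 (-0.26 ± 0.06) were lower in brachial scrapes, HOXD12 was higher (0.21 ± 0.05) and 2 did not pass. Camera called neither list (adjusted p = 0.411 and 0.357, and 0.994 for both with an estimated correlation), while fry gave adjusted p = 3.14e-06 and 0.00539. Between the arteries fry called 14 of 33 lists. As for all differences between arteries, a hybridisation batch cannot be told apart from artery here. Of 26 matrix genes 11 were higher in brachial scrapes, 1 lower and 14 not passing, with COL8A1 at 0.87 ± 0.07 and the gelatinase MMP2 at 0.47 ± 0.06 (camera adjusted p = 0.0665, and adjusted p = 0.994 with an estimated correlation).

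Vasoactive and antioxidant genes also parted the arteries in single members. Of 9 endothelin and angiotensin genes 4 were higher in brachial scrapes, 3 lower and 2 not passing, and of 23 antioxidant genes 7, 7 and 9, with the same numbers when adjusted over each list alone (camera adjusted p = 0.886 and 0.93, and 0.994 for both with an estimated correlation). Extracellular dismutase SOD3 was higher in brachial scrapes (1.31 ± 0.08, adjusted p = 6.82e-14), as were angiotensin-converting enzyme ACE (0.69 ± 0.06) and the angiotensin receptor AGTR1 (1.41 ± 0.33, adjusted p = 0.00075), while endothelin-converting enzyme ECE1 was lower (-0.69 ± 0.12). The related shear-responsive factors KLF2 and KLF4 went opposite ways, at 0.51 ± 0.09 and -0.55 ± 0.10. With training, averaged over arteries, 511 of 6765 genes of any kind passed. Among them were single members of lists that camera did not call, with 23 antioxidant, 18 mitochondrial, 9 vasoconstriction, 16 glycolysis and 15 vasodilation genes measured. No test asked whether members of these lists passed more often than genes of any kind. PRDX5, a peroxiredoxin (0.61 ± 0.11, adjusted p = 0.00268), SIRT3 (0.49 ± 0.07, adjusted p = 0.000374), the adrenergic receptor ADRA2A (0.53 ± 0.11), the glycolytic enzymes ALDOC (0.54 ± 0.10) and PFKM (0.38 ± 0.08), and the prostaglandin synthase PTGS1 (0.50 ± 0.14, adjusted p = 0.0426) rose, and the glycolytic enzyme PGK1 fell (-0.20 ± 0.05).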
